A study of Drosophila mojavensis mojavensis and Drosophila mojavensis wrigleyi and Drosophila mojavensis sonorensis with 44 samples.

How the data were processed

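Gene expression was measured in wandering larvae of the final instar of the cactophilic fly Drosophila mojavensis, with 1-colour microarrays made by NimbleGen. The labels name 4 subspecies (mojavensis, wrigleyi, baja and sonorensis) and 22 isofemale lines, each line being the descendants of a single wild-caught female. There were 6 lines of mojavensis, 6 of wrigleyi, 4 of baja and 6 of sonorensis, and 2 arrays per line, 44 arrays in all. Per the labels' protocols, all lines were reared alike at 25 °C with 12 hours of light, larvae were collected approximately 8 days after egg laying in groups of 20 per tube, and total RNA was extracted and amplified to antisense RNA before labelling with Cy3. The labels do not say whether the 2 arrays of a line came from separate tubes. The sample titles give the 2 arrays of a line different numbers after the letter L, and these numbers were not used here.

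The deposited intensity values are unnormalized scanner readings of single perfect-match probes, extracted with NimbleScan 2.4.31 per the file headers. The mismatch column summed to 0 and was not used. The submitters' processing notes name RMA, but 100% of the values in the deposited series table were equal to the scanner intensity of the same probe, so that table held no normalized values. It was run as an alternative, as log2 intensity with no background correction or normalization. Each array held 71998 probes for 14519 targets, each target being a predicted transcript. Of these, 13925 targets had 5 probes, 592 had 4, and the other 2 had 3 and 2 probes. No random control probes were used here, so no target could be called above or below background.

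From the intensities, background was corrected with the normexp method of limma 3.58.1 (offset 50), run in R 4.3.3 with the data.table package (version 1.17.8). Values were then put on the log2 scale, quantile-normalized over all probes and arrays, and summarised per target by median polish. The 2 arrays of a line were averaged, since they come from the same line and the line is the unit that represents a subspecies. The line names of each subspecies begin with a single code (ANZA, CI, MJBC or OPNM). If a code stands for a single collection, a subspecies cannot be told apart from its collection. Groups were compared with lmFit, contrasts.fit and eBayes of limma over all 22 lines in a single fit with 18 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each contrast. The threshold was an adjusted p of 0.05. The tests were an F test among the 4 subspecies, the 6 pairs, and, for each subspecies, the targets that differed from each of the other 3 in the same direction, called set apart here. The size of such a difference is that to the mean of the other 3. Lines within subspecies were compared by an F test on single arrays, in which the arrays of a line give the error. The share of variance between subspecies was tested with 100000 permutations of the lines over the groups, one-sided. A p-value here measures the spread between lines, or between arrays of a line, and the number of arrays limits the precision. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

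The fit was tested on simulated data for all 14519 targets, of which 200 were changed by a known amount in 1 subspecies. For sonorensis against wrigleyi it recovered 15% of changes of 0.5 on the log2 scale, 80.5% of changes of 1 and 99% of changes of 2. For baja against wrigleyi, with fewer lines, it recovered 9.5%, 75.5% and 98%. False calls made up at most 5.85% of calls. The simulated noise was normal and independent between targets, without deviations that many targets of a line share. The rate of false calls in the real data is therefore not known from it.

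The rule for named genes, written before the data were examined, gave places to genes with a description in the reference table: the 10 highest and 10 lowest set apart in each subspecies, up to 3 per gene list and subspecies, the 3 highest and 3 lowest per pair, the alcohol dehydrogenase and glutathione S-transferase D1 genes whatever their result, and the 5 with the smallest p among lines. If the reference gave no descriptions, identifiers were to take the places, with at most 2 higher and 2 lower printed per comparison. The array gives 14471 targets a GI number and 48 another name, and the RefSeq table used for this species held no GI number, so the second part of the rule was used. The 48 named targets are reported as a group, a choice made after the array's names had been seen. They are 25 targets whose names start with Tes, 10 that start with Acp or moj, and 13 others, of which 1 is not reported here. Of 29 gene lists fixed beforehand, matched by name, 2 had any member on the array (alcohol and aldehyde dehydrogenases, with Adh1 and Adh2, and seminal fluid proteins, with Acp11, Acp2, Acp48 and Acp7) and 0 had the 5 members needed for a test. The planned list test was therefore replaced by camera (preset inter-gene correlation 0.01) and fry on the Tes group and on the Acp or moj group. These lists were chosen after the array's names had been seen.

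The median raw intensity of an array ran from 586 to 1846, and 0 to 88 probes per array were at the scanner's upper limit of 65535. Between 2 arrays of a line the correlation over targets had a median of 0.978. For 2 arrays the median correlation with the other arrays was under 0.9, namely baja MJBC-103 replicate 1 (0.822) and sonorensis OPNM-407-10 replicate 1 (0.771), and each count was also run without them. Arrays were extracted on 2 days, with 6 arrays on the second (4 sonorensis, 1 wrigleyi and 1 baja). The second day held too few arrays to be analysed alone, so the day was fitted as a block and the first day was analysed alone. Sonorensis arrays came at places 29 to 44 of the order of extraction and mojavensis arrays at places 1 to 27. No slide held over 1 array. The labels give every line a replicate 1 and a replicate 2. Deviations of same-numbered arrays from their line means had correlations from -0.722 to 0.822 over 231 pairs of lines, with 129 pairs over 0.1. No chance range was computed for these, so a shared effect of the numbers is not excluded. The main fit did not pair the arrays by number, and a replicate block was run as an alternative.

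Alternatives fixed before the data were examined were no background correction, normexp without offset, median scaling, cyclic loess, the mean of the probes, the deposited table, omission of dim targets (mean level under the first quartile), omission of 2844 probes in 2383 targets whose subspecies difference departed from that of their target by more than 1, single arrays with and without the line as random block, a replicate block, an extraction day block, trended robust moderation, array weights, each line left out, fits of 2 subspecies alone, and a minimum log2 difference of 1. Omission of departing probes left 5 targets with no probe. Alternatives added after seeing the data were omission of the 2 doubted arrays, raw signal as a covariate (also with each line left out, for targets set apart), 100 draws of 4 lines per subspecies, the first day alone, and the background correction of RMA.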

Results

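Larval expression profiles were obtained for the 4 cactus host races of Drosophila mojavensis. As background, mojavensis breeds on barrel cactus in the Mojave Desert, wrigleyi on prickly pear on Santa Catalina Island, baja on agria cactus in Baja California and sonorensis on organ pipe cactus in mainland Sonora. All lines had been raised on the same food, so the comparisons address inherited differences between the lines of the races and not direct effects of the host plant. The line names of each race share a code, so race and collection may not be separable. The arrays were not equally bright. The mean log2 median raw intensity per line was 9.93 ± 0.30 (SD, n = 6 lines) in mojavensis, 10.26 ± 0.21 (n = 6) in wrigleyi, 10.20 ± 0.34 (n = 4) in baja and 9.56 ± 0.17 (n = 6) in sonorensis, so the sonorensis arrays were the dimmest. They were also processed late, at places 29 to 44 in the order of extraction, against 1 to 27 for mojavensis, 3 to 43 for wrigleyi and 4 to 39 for baja. All values below are normalized log2 levels, averaged over the 2 arrays of a line. A range after an SE is that of the log2 difference over the alternative settings. For targets with a GI number, and for Tes113 and per, no fold is given, since the level of a dim group over background could not be judged. The folds of other named targets carry the same doubt where a group is dim.

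Expression differed widely among the subspecies. The limma F test called 5545 of 14519 targets (38.2%), 21 of the 48 named targets among them (21 also when adjusted over the list alone). These 21 were 14 of the 25 Tes targets, 2 of the 10 Acp or moj targets (moj29 and moj9), and 5 of the other 13, namely the alcohol dehydrogenase genes Adh1 and Adh2, the xanthine dehydrogenase gene Xdh, the circadian clock gene per and the cell adhesion gene Dscam. The subspecies accounted for 42.2% of the variance among line means, where chance gives 14.3% (permutation p = 1e-05, one-sided, the smallest that 100000 permutations can give). On the first principal component, which held 32.8% of the variance, the 6 sonorensis lines lay between -52.7 and -31.7 and the other 16 lines between -19.9 and 56.2. Lines ANZA-0402-10, CI-1002-27 and MJBC-103, which lay farthest from the other lines of mojavensis, wrigleyi and baja, had the highest log2 median raw intensity of their subspecies (10.47, 10.66 and 10.71). They also had the highest scores of their subspecies on the first component (36.3, 56.2 and 52.9), while the brightest sonorensis line did not. Since sonorensis was the dimmest group, its place on this component cannot be told apart from array brightness.

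**Figure D1:**
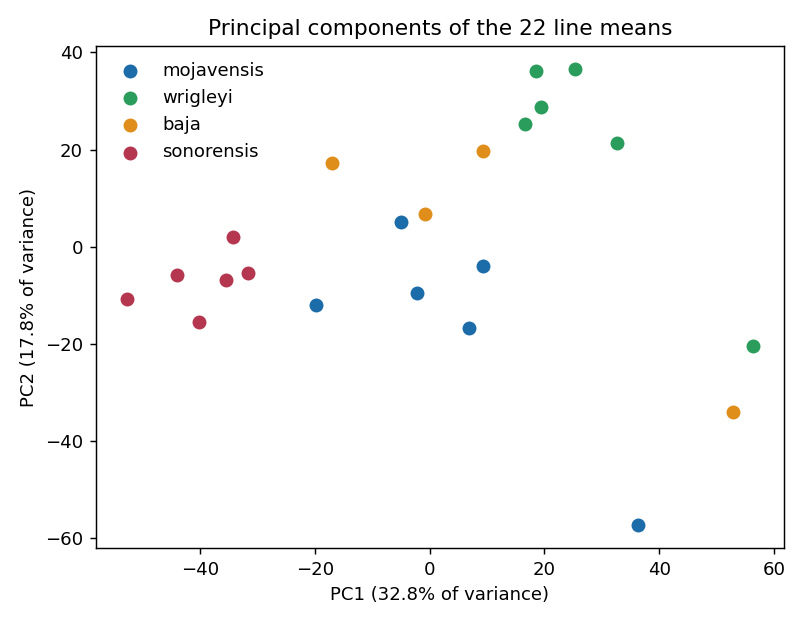
Scores of the 22 line means on principal components 1 (32.8% of variance) and 2 (17.8%), in arbitrary units, coloured by subspecies. The 6 sonorensis lines lie at the left, from -52.7 to -31.7 on component 1, apart from the other 16 lines. Their arrays were also the dimmest.

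The alcohol dehydrogenase genes separated sonorensis from wrigleyi. Their enzymes oxidise ethanol and other alcohols, which are abundant in fermenting cactus tissue. Adh1 stood at 14.19 ± 0.18 (SD, n = 6) in sonorensis, 13.14 ± 0.75 (n = 6) in mojavensis, 12.72 ± 0.81 (n = 4) in baja and 12.34 ± 0.58 (n = 6) in wrigleyi. Adh2 stood at 15.21 ± 0.17 in sonorensis, 14.30 ± 0.88 in mojavensis, 13.81 ± 0.91 in baja and 13.14 ± 0.61 in wrigleyi. Between sonorensis and wrigleyi, Adh1 was 3.62-fold higher in sonorensis (log2 difference 1.86, SE 0.33, range 1.24 to 2.23, limma adjusted p = 0.000173) and Adh2 4.19-fold (2.07, SE 0.37, range 1.53 to 2.41, adjusted p = 0.000186). No wrigleyi line reached the lowest sonorensis line in either gene. Against the mean of the other 3, both were higher in sonorensis (adjusted p = 0.000392 for Adh1 and 0.00101 for Adh2) and lower in wrigleyi (adjusted p = 0.0112 and 0.00468). Both were also lower in baja than in sonorensis, Adh1 by 1.47 and Adh2 by 1.40 on the log2 scale (adjusted p = 0.0101 and 0.0226), calls that ended without baja line MJBC-155 (adjusted p = 0.0540 and 0.120), with the extraction day as a block (0.0675 and 0.151) and with raw signal as a covariate (0.0825 and 0.0902), and for Adh2 also with the line as random block (0.102), the replicate block (0.0989) and the first day alone (0.0585). The differences between baja and sonorensis were -1.49 and -1.36 with the day block, -1.36 and -1.48 with the covariate, and -1.07 and -0.95 without MJBC-155. With the day block the contrasts of wrigleyi with the others had adjusted p of 0.0858 and 0.0657, and that of Adh1 had 0.0585 with the line as random block and 0.0533 with the deposited values. In 3 lines, 1 each of mojavensis, wrigleyi and baja, both genes were far lower on 1 array of the line than on the other.

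**Figure D2:**
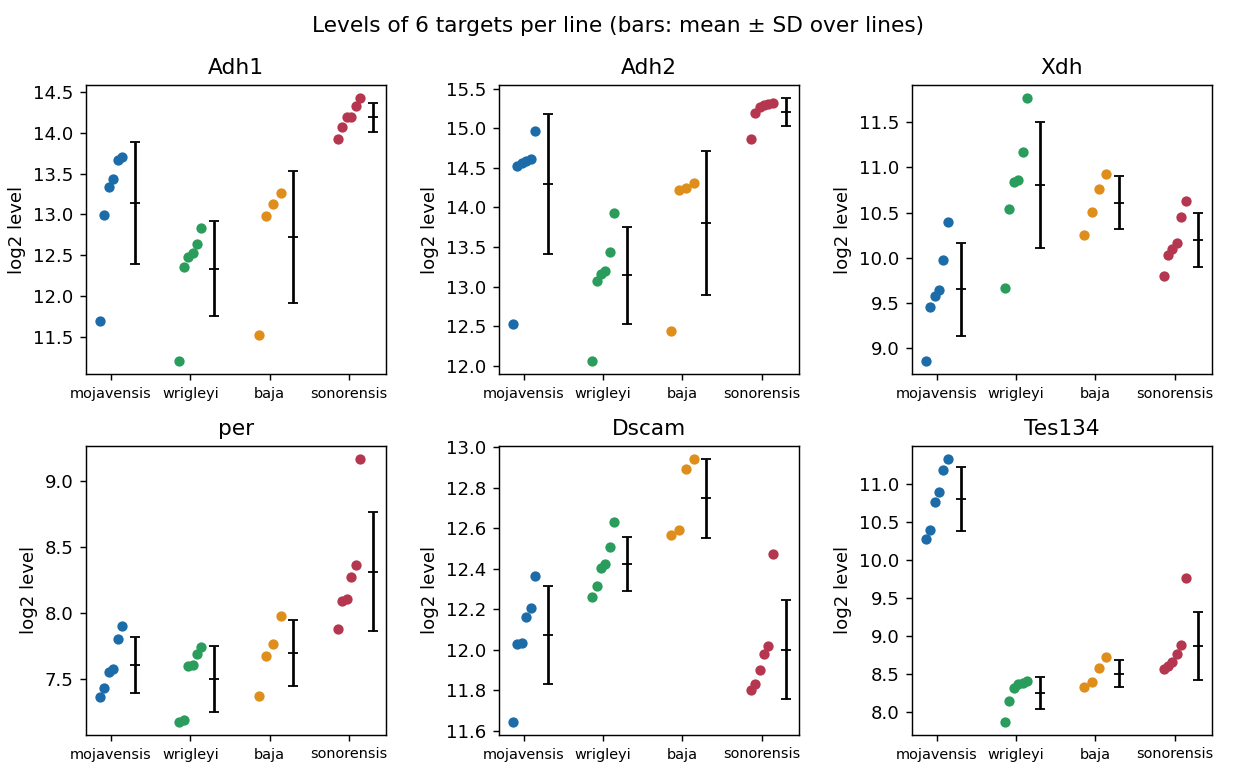
Normalized log2 levels of Adh1, Adh2, Xdh, per, Dscam and Tes134 for each line (points, 6, 6, 4 and 6 lines), with the mean ± SD of the subspecies. Adh1 and Adh2 are highest in sonorensis, at 14.19 and 15.21, and Tes134 is highest in mojavensis, at 10.80.

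Among the Tes targets, the largest named group, more were lower than higher in sonorensis. The prefix marks transcripts found in testis in earlier work on this species. Against the mean of the other subspecies, 13 of the 25 Tes targets were lower in sonorensis, 1 was higher (Tes14, at -0.13 in the deposited table without normalization and with an adjusted p of 0.172 with the extraction day block) and 11 did not pass, and the counts were the same when adjusted over the list alone. Over the alternatives the call of Tes106 (adjusted p = 0.0426) was lost in 16 of 40, that of Tes14 in 7, of Tes40 in 5, of Tes124 in 2 of 39 and of each of the other 10 in at most 1. The largest differences were in Tes113 (log2 difference -1.60, SE 0.18, range -2.24 to -0.92, adjusted p = 2.39e-06) and Tes118, 2.89-fold lower (-1.53, SE 0.20, range -1.98 to -0.76, adjusted p = 1.83e-05). In wrigleyi 8 Tes targets were higher and 2 lower (Tes14 and Tes134), and the call was lost for Tes101 in 10 of 40 alternatives, Tes105 in 8, Tes127 in 6 and each of the other 7 in at most 1. Tes118 stood at 11.09 ± 0.39 (SD, n = 6) in wrigleyi, 10.13 ± 0.39 (n = 4) in baja, 10.02 ± 0.48 (n = 6) in mojavensis and 8.88 ± 0.51 (n = 6) in sonorensis. As a group, Tes targets had a median log2 difference of -0.37 in sonorensis (camera adjusted p = 0.000226 over 8 tests) and 0.20 in wrigleyi (adjusted p = 0.0169), against medians of -0.0018 and -0.014 over all targets. With an estimated inter-gene correlation the adjusted p were 0.627 and 0.815, so neither group call held. The fry test, which asks whether the targets of the group move on balance 1 way, gave adjusted p of 0.000897 in sonorensis and 0.0486 in wrigleyi. In mojavensis the group's preset-correlation adjusted p was 0.0479, with 3 members higher, and the adjusted p was 0.815 with an estimated correlation. With raw signal as a covariate, 4 Tes targets passed as lower in sonorensis (Tes113, Tes118, Tes129 and Tes154, all among the 13) and 2 as higher (Tes104, 0.93, and Tes33, 0.48, adjusted p = 0.0226 and 0.0469). In wrigleyi 3 of the 8 then passed as higher (Tes113, Tes118 and Tes154), and 5 targets passed as lower (Tes14, Tes134, Tes104, Tes106 and Tes33). With that covariate the median of the group in sonorensis was -0.11 (camera p = 0.339, unadjusted), and Tes106, Tes120 and Tes124 turned to 0.42, 0.16 and 0.056.

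**Figure D3:**
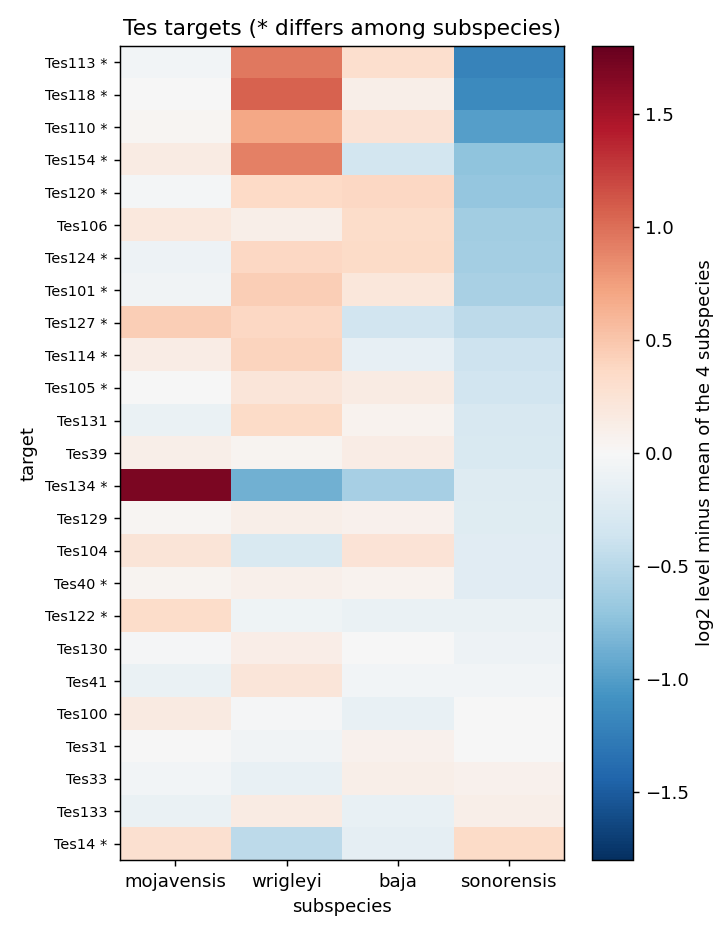
Mean log2 level of the 25 Tes targets in each subspecies minus the mean of the 4 subspecies (colour scale, red higher and blue lower), ordered by the value in sonorensis. An asterisk marks the 14 targets called among the subspecies. The strongest red cell is Tes134 in mojavensis and the strongest blue cells are Tes113 and Tes118 in sonorensis.

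Tes134 was highest in mojavensis. It was 4.79-fold higher in mojavensis than in the mean of the others (log2 difference 2.26, SE 0.16, range 2.00 to 2.99, adjusted p = 1.21e-08), with 10.80 ± 0.42 (SD, n = 6) against 8.25 ± 0.21 (n = 6) in wrigleyi, 8.51 ± 0.17 (n = 4) in baja and 8.87 ± 0.45 (n = 6) in sonorensis. The lowest mojavensis line, at 10.27, lay above the highest line of any other subspecies, at 9.76. It was lower in wrigleyi and in baja than in the mean of the others (adjusted p = 6.32e-05 and 0.0344), and the baja call ended without line MJBC-103 or MJBC-155 (0.117 and 0.150), on the first day alone (0.170), with raw signal as a covariate (0.0528) and with the deposited values (0.0912).

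The Acp or moj targets showed little difference in the main analysis. The name Acp stands for accessory gland proteins of the seminal fluid, and none of the 4 Acp targets passed a contrast of 1 subspecies with the others. With raw signal as a covariate 3 of them did: Acp11 was higher in sonorensis (1.09, adjusted p = 0.0194, against -0.29 without it) and lower in wrigleyi (-0.94, adjusted p = 0.00992), Acp48 was higher in sonorensis (0.61, adjusted p = 0.00579) and Acp2 was lower in wrigleyi (-1.04, adjusted p = 0.00273). Of the 6 moj targets, moj29 was 1.25-fold lower in mojavensis (adjusted p = 0.0307), and moj30 and moj9 were 1.42-fold and 1.29-fold higher in sonorensis (adjusted p = 0.0310 and 0.0187), but stood at -0.061 and -0.046 in the deposited table without normalization. With raw signal as a covariate the log2 differences of moj30 and moj9 were 0.051 and 0.13, and neither passed, while moj32 passed as lower in sonorensis (-0.44, adjusted p = 0.0490) and moj29 as higher in wrigleyi (0.30, adjusted p = 0.0340). With the extraction day block the calls of moj29, moj30 and moj9 ended (adjusted p = 0.0637, 0.0666 and 0.0719), as they did on the first day alone (0.288, 0.295 and 0.0612). The call of moj29 also ended under median scaling (0.667), with the deposited values (0.379) and without ANZA-0402-3, ANZA-0402-4, ANZA-0402-8 or ANZA-0402-10 (adjusted p = 0.0570, 0.0822, 0.0621 and 0.0845), and that of moj30 without the offset (0.0719), with the RMA background (0.0685) and without OPNM-407-2, OPNM-407-5 or OPNM-407-8 (0.0967, 0.0680 and 0.0971). The camera adjusted p of the group was 0.949 in each subspecies, and its median and mean differed in sign in mojavensis (0.0048 and -0.0081), wrigleyi (0.0082 and -0.029) and baja (-0.010 and 0.039). In sonorensis both were negative (-0.030 and -0.0025) while the camera direction was up.

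Of the other named targets, Xdh was lowest in mojavensis. Its enzyme, xanthine dehydrogenase, acts in purine breakdown and eye pigment synthesis. Its level was 9.65 ± 0.52 (SD, n = 6) in mojavensis, 10.81 ± 0.70 (n = 6) in wrigleyi, 10.61 ± 0.29 (n = 4) in baja and 10.19 ± 0.30 (n = 6) in sonorensis. The wrigleyi level was 2.23-fold above that of mojavensis (log2 difference 1.16, SE 0.27, adjusted p = 0.00688). The clock gene per was higher in sonorensis than in the mean of the others (log2 difference 0.71, SE 0.15, range 0.087 to 1.13, adjusted p = 0.000896), but by 0.087 with the deposited values without normalization (adjusted p = 0.671). Dscam, which encodes a cell adhesion protein of neurons, was higher in baja (log2 difference 0.58, SE 0.12, range 0.47 to 0.77, adjusted p = 0.0202) and 1.33-fold lower in sonorensis (adjusted p = 0.00506), where the call ended under median scaling (-0.30, adjusted p = 0.160) and with raw signal as a covariate (-0.44, adjusted p = 0.0522). The corepressor gene CtBP was 1.13-fold lower in sonorensis (adjusted p = 0.0459), and 0.030 higher on the log2 scale under median scaling, and its call ended in 24 of 40 alternatives. The targets beta4GalT7, cbt, Marf, snf, ST6Gal and Trap100 passed neither the F test nor a contrast of 1 subspecies with the others, although Trap100 was higher in wrigleyi with raw signal as a covariate (0.41, adjusted p = 0.0353). With the extraction day as a block, the contrast of mojavensis with the others for Xdh no longer passed (log2 difference -0.79, adjusted p = 0.0764), nor did it on the first day alone (-0.74, adjusted p = 0.280), and that of Dscam in baja did not pass on the first day alone (0.50, adjusted p = 0.261), under median scaling (0.47, adjusted p = 0.302) or without MJBC-35, MJBC-103 or MJBC-155 (adjusted p = 0.0533, 0.0517 and 0.124). The Xdh call also ended without ANZA-0402-4, ANZA-0402-8, ANZA-0402-10 or ANZA-0402-17 (adjusted p = 0.0553, 0.0512, 0.0747 and 0.0518).

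Sonorensis and wrigleyi were the most distant pair. They were also the dimmest and the brightest group (mean log2 median raw intensity 9.56 and 10.26). The rank of this pair therefore cannot be told apart from array brightness. Of the named targets, 7 were higher in sonorensis, among them Adh1, Adh2, per and Tes134, and 15 were lower, 13 of them Tes targets. Over all targets 5459 differed, 2822 higher and 2637 lower in sonorensis, 1235 of them by at least 1 on the log2 scale. GI10590 was higher in sonorensis (log2 difference 4.05, SE 0.24, range 2.98 to 5.50, adjusted p = 4.94e-10), as was GI18000 (3.94, SE 0.39, range 3.18 to 4.74, adjusted p = 3.26e-07). GI14480 was lower (-5.01, SE 0.26, range -6.26 to -4.42, adjusted p = 7.02e-11), as was GI14738 (-4.43, SE 0.72, range -5.45 to -3.91, adjusted p = 7.97e-05). The files do not pair these numbers with gene names. After removal of the error between lines, the SD of the differences over targets was 0.58 on the log2 scale, the widest of the 6 pairs. Under median scaling, where the median over all targets was 0.14, 3583 targets were higher and 1475 lower. In the deposited table without normalization the median was -0.54, with 280 higher and 8053 lower.

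Sonorensis and mojavensis differed in 3143 targets, 1736 higher and 1407 lower in sonorensis. Adh1 was 2.08-fold higher in sonorensis (log2 difference 1.05, SE 0.33, range 0.65 to 1.25, adjusted p = 0.0255), a call that ended without mojavensis line ANZA-0402-5 (0.77, adjusted p = 0.0649) or sonorensis line OPNM-407-2 (1.01, adjusted p = 0.0527), with the line as random block (0.0912), the replicate block (0.0790) or the extraction day block (0.130), with raw signal as a covariate (0.0872) and with the deposited values (0.156). Adh2 did not pass (0.91, adjusted p = 0.0758), and per was higher. The 10 named targets that were lower were all Tes targets, led by Tes134 (3.81-fold) and Tes113. GI21837 was higher in sonorensis (log2 difference 4.42, SE 0.24, range 3.23 to 5.98, adjusted p = 5.55e-11), although 1 of its 5 probes did not go that way, and GI16676 was higher as well (4.11, SE 0.19, range 3.86 to 4.37, adjusted p = 5.22e-12). GI10868 was lower (-4.26, SE 0.57, range -5.35 to -3.70, adjusted p = 9.14e-05), as was GI22796 (-2.44, SE 0.46, range -3.48 to -2.02, adjusted p = 0.00152). With raw signal as a covariate the count was 1783, and under median scaling 1708 targets were higher and 789 lower.

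Wrigleyi and mojavensis differed in 1917 targets, 1078 higher and 839 lower in wrigleyi. Xdh, moj29, Tes154, Tes113 and Tes118 were higher in wrigleyi, and Tes134, Tes14, Tes122 and Adh2 were lower. Adh2 was 2.22-fold lower (log2 difference -1.15, SE 0.37, range -1.51 to -0.94, adjusted p = 0.0394) and missed the threshold in 16 of 40 alternatives, among them the line as random block (adjusted p = 0.161), the replicate block (0.156), the extraction day block (0.216) and 9 with a single line left out, CI-1002-6 being one (-0.94, adjusted p = 0.108), and Adh1 did not pass (-0.80, adjusted p = 0.110). The largest differences were in GI15361, higher in wrigleyi (5.35, SE 0.80, range 4.54 to 6.40, adjusted p = 0.000247), and GI21837, also higher (4.36, SE 0.24, range 3.47 to 5.89, adjusted p = 7.49e-11). GI23249 was lower (-3.37, SE 0.60, range -3.87 to -2.79, adjusted p = 0.000986), as was GI14514 (-3.28, SE 0.61, range -3.70 to -2.68, adjusted p = 0.00144). The count was 3605 with raw signal as a covariate and 1267 without mojavensis line ANZA-0402-4, and under median scaling 541 targets were higher and 805 lower.

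**Figure D4:**
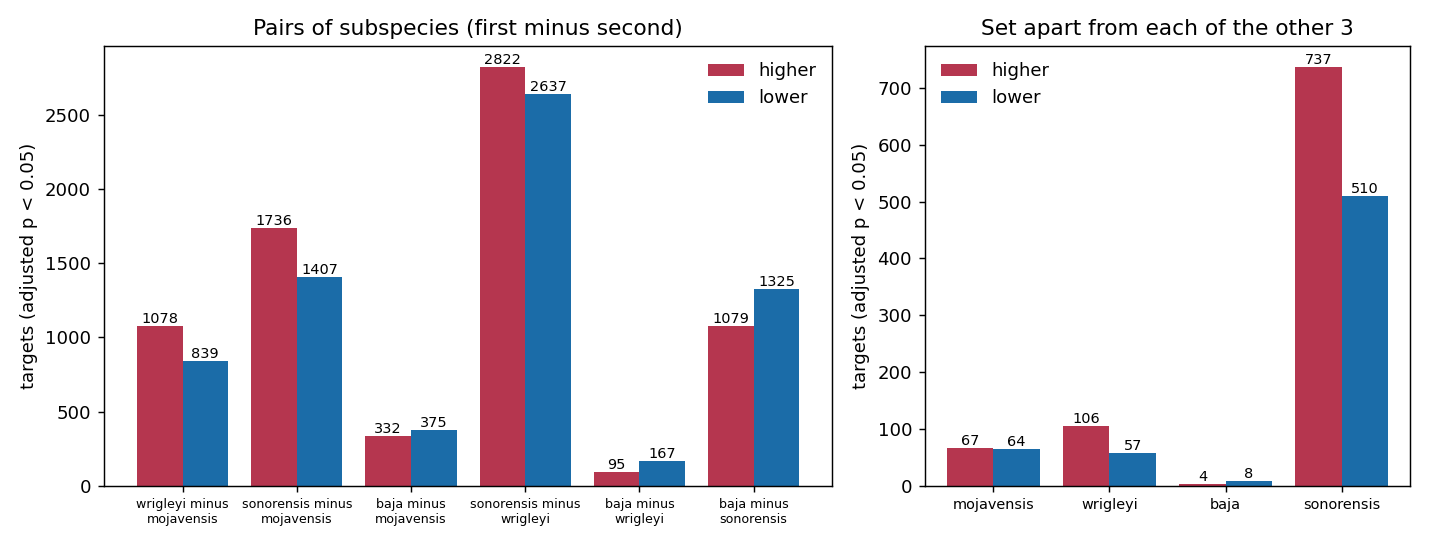
Number of targets past an adjusted p of 0.05 in each of the 6 pairs, higher or lower in the first subspecies of the pair (left), and number set apart from each of the other 3 subspecies (right). The most targets differed between sonorensis and wrigleyi (2822 higher, 2637 lower), and sonorensis had the most set apart (737 higher, 510 lower).

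Baja was represented by 4 lines. Against sonorensis 2404 targets differed, 1079 higher and 1325 lower in baja. Among these, Dscam and 7 Tes targets were higher in baja, and Adh1, Adh2, per and moj9 were lower. GI14738 was higher (log2 difference 3.02, SE 0.80, range 2.41 to 3.97, adjusted p = 0.0144), as was GI14556 (2.84, SE 0.88, range 2.26 to 3.75, adjusted p = 0.0307), and GI21954 was lower (-3.46, SE 0.31, range -3.90 to -2.69, adjusted p = 9.63e-07), as was GI18936 (-3.02, SE 0.59, range -3.70 to -2.20, adjusted p = 0.00235). The count was 1115 without baja line MJBC-103, 1418 without MJBC-155, 1152 with raw signal as a covariate, 753 in a fit of the 2 subspecies alone and 6898 with the deposited values, and under median scaling 487 targets were higher and 1798 lower. The calls of GI14738 and GI14556 ended without MJBC-103 (adjusted p = 0.0617 and 0.0972) and with raw signal as a covariate (0.0522 and 0.0905), and that of GI14556 also with array weights (0.102), with cyclic loess (0.0578), without the 2 doubted arrays (0.0551) and without MJBC-35, MJBC-216, OPNM-407-2 or OPNM-407-5 (0.0618, 0.0532, 0.0545 and 0.0517). The log2 differences of GI14738 and GI14556 were 3.47 and 3.17 with the covariate, and 2.70 and 2.59 without MJBC-103.

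Against mojavensis 707 targets differed, 332 higher and 375 lower in baja. Dscam was 1.59-fold higher in baja (adjusted p = 0.00860), Tes134 was 4.91-fold lower (adjusted p = 2.40e-06) and Tes127 was 1.71-fold lower (adjusted p = 0.0314), while Adh1 and Adh2 did not pass (-0.41 and -0.49, adjusted p = 0.624 and 0.594). GI14494 was higher (log2 difference 5.24, SE 0.70, range 4.35 to 6.90, adjusted p = 0.000154), as was GI20893 (4.45, SE 0.61, range 3.73 to 6.02, adjusted p = 0.000206). GI10868 was lower (-4.60, SE 0.64, range -5.82 to -3.95, adjusted p = 0.000219), as was GI22796 (-3.83, SE 0.52, range -5.08 to -3.17, adjusted p = 0.000168). The count was 2142 without the 2 doubted arrays, 1714 with raw signal as a covariate, 311 in a fit of the 2 subspecies alone, 133 on the first day alone, 284 without baja line MJBC-155 and 1077 without sonorensis line OPNM-407-10. Under median scaling 98 targets were higher and 205 lower.

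Baja and wrigleyi had the fewest targets called in the main analysis, 262, of which 95 were higher and 167 lower in baja. The only named target called was Tes154, 2.35-fold lower in baja (log2 difference -1.23, SE 0.23, adjusted p = 0.00623). GI20893 was higher in baja (3.87, SE 0.61, range 3.30 to 5.16, adjusted p = 0.00171), as was GI24821 (2.95, SE 0.72, range 2.36 to 3.39, adjusted p = 0.0348), although 1 of the 5 probes of GI24821 went the other way (-0.67). GI15361 was lower (-5.09, SE 0.89, range -6.15 to -4.60, adjusted p = 0.00414), as was GI14480 (-3.67, SE 0.29, range -4.17 to -3.38, adjusted p = 1.60e-07). The call of GI24821 ended without CI-1002-8, CI-1002-9 or any 1 of the 4 baja lines (adjusted p from 0.0510 to 0.109), under median scaling (0.0668), with the RMA background (0.0609), with the mean of the probes (0.0895) and with the deposited values (0.101). The SD of the differences over targets, corrected for error, was 0.26 (0.23 to 0.29 with 1 line left out), against 0.30 (0.27 to 0.33) for baja and mojavensis. Adh1 and Adh2 did not pass (0.39 and 0.66, adjusted p = 0.688 and 0.498). The count was 711 without the 2 doubted arrays, 607 with raw signal as a covariate, 530 without sonorensis line OPNM-407-10, 169 without MJBC-155, 174 each without MJBC-35 and CI-1002-6, 164 without CI-1002-23 and 149 without CI-1002-9.

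Because baja had fewer lines, the counts were also taken from 100 draws of 4 lines per subspecies. The median count was 3475.5 (range over the draws 2438 to 4457) for sonorensis and wrigleyi, 1099 (202 to 2762) for sonorensis and mojavensis, 1424.5 (321 to 2761) for baja and sonorensis, 640 (155 to 1842) for wrigleyi and mojavensis, 238.5 (88 to 864) for baja and mojavensis, and 106 (20 to 546) for baja and wrigleyi. These ranges overlapped, so the draws do not rank neighbouring pairs.

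Sonorensis was set apart from each of the other 3 in 1247 targets, 737 higher and 510 lower. Of the named targets, 6 were higher (Adh1, Adh2, moj30, moj9, per and Tes14) and 15 lower (CtBP, Dscam and 13 Tes targets) than the mean of the others. That contrast is looser than being set apart. Against mojavensis only Adh1 and per passed as higher and 10 Tes targets as lower, so no other named target was set apart in sonorensis. Adh1 and per passed against wrigleyi and baja as well. Of the 10 Tes targets at most 7 were set apart, since only 7 Tes targets passed against baja. GI10590 was higher in sonorensis (log2 difference 3.11, SE 0.20, range 2.26 to 4.07, adjusted p = 2.66e-09), as was GI16640 (3.09, SE 0.33, range 2.26 to 3.86, adjusted p = 1.45e-06), and GI14480 was lower (-2.52, SE 0.22, range -3.45 to -2.04, adjusted p = 2.49e-07), as was GI18617 (-2.15, SE 0.25, range -2.95 to -1.20, adjusted p = 3.42e-06). The count was 377 with raw signal as a covariate, 757 without the 2 doubted arrays, 623 without MJBC-103, 826 without MJBC-155 and 820 without OPNM-407-2, and under median scaling 1018 targets were higher and 266 lower. With dim targets left out 300 were higher and 435 lower, and with the deposited values 31 were higher and 2720 lower.

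Wrigleyi was set apart in 163 targets, 106 higher and 57 lower. The named targets higher in wrigleyi than in the mean of the others were Xdh and 8 Tes targets, and Adh1, Adh2, Tes14 and Tes134 were lower. That contrast is looser than being set apart. Of the named targets only Tes154 was called between baja and wrigleyi, so no other was set apart in wrigleyi. GI15361 was higher (log2 difference 4.75, SE 0.66, range 3.85 to 5.67, adjusted p = 5.94e-05), with a spread of 2.06 (SD, n = 6) among wrigleyi lines, and GI14480 was higher (4.15, SE 0.22, range 3.85 to 4.90, adjusted p = 7.66e-11). GI23249 was lower (-3.26, SE 0.50, range -3.76 to -2.71, adjusted p = 0.000131), as was GI14514 (-3.09, SE 0.51, range -3.50 to -2.55, adjusted p = 0.000256). The count was 255 without the 2 doubted arrays, 281 with raw signal as a covariate, 106 with the extraction day block, 311 without OPNM-407-10, 107 without MJBC-155, 96 without MJBC-216, 88 without MJBC-35, 84 without CI-1002-9, 100 without CI-1002-23 and 102 without CI-1002-6. The call of Xdh in wrigleyi (adjusted p = 0.0448) ended in 23 of 40 alternatives.

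Mojavensis was set apart in 131 targets, 67 higher and 64 lower. Tes134, Tes127 and Tes122 were higher in mojavensis than in the mean of the others, and Xdh and moj29 were lower. That contrast is looser than being set apart, and among these targets only Tes134 was called against both wrigleyi and baja. The call of Tes127 ended without ANZA-0402-3, ANZA-0402-4, ANZA-0402-8 or ANZA-0402-17 (adjusted p = 0.0567, 0.0643, 0.0693 and 0.0621), with the extraction day block (0.0520), on the first day alone (0.293) and with the deposited values (0.240). The call of Tes122 ended without ANZA-0402-8 (0.0542), under median scaling (0.111), on the first day alone (0.112) and with the deposited values (0.0847). GI14494 was lower (log2 difference -4.47, SE 0.52, range -5.97 to -3.65, adjusted p = 2.34e-05), as was GI21837 (-4.40, SE 0.20, range -5.95 to -3.51, adjusted p = 1.39e-12), the latter by 4 of its 5 probes, and no line of another subspecies was as low in either. GI10868 was higher (3.57, SE 0.47, range 3.10 to 4.44, adjusted p = 0.000103), as was GI22796 (2.65, SE 0.38, range 2.33 to 3.63, adjusted p = 0.000242). The count was 282 without the 2 doubted arrays and 85 without MJBC-155, and under median scaling 51 targets were higher and 25 lower.

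Baja was set apart in 12 targets, 4 higher and 8 lower. GI24425 was higher in baja (log2 difference 0.92, SE 0.16, range 0.65 to 1.38, adjusted p = 0.00703) and GI24027 was higher by 0.85 (SE 0.17, range 0.62 to 1.13, adjusted p = 0.0188). GI14479 was lower (-2.54, SE 0.45, range -3.08 to -1.90, adjusted p = 0.00749), as was GI24725 (-1.49, SE 0.15, range -1.64 to -1.30, adjusted p = 3.83e-05). The count was 83 without the 2 doubted arrays, 36 with the replicate block, 22 with the extraction day block, 7 without MJBC-103, 25 without MJBC-216, 34 without MJBC-35 and 35 without OPNM-407-10, and the call of GI24027 ended without MJBC-103 (adjusted p = 0.0888), on the first day alone (0.157), under median scaling (0.111), with the mean of the probes (0.0535) and with the deposited values (0.0541).

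Lines of the same subspecies differed in 2773 targets (19.1%), and 2241 of these were not called among the subspecies. Among the named targets 8 differed between lines, namely Acp11, Acp2, beta4GalT7, Tes104, Tes106, Tes124, Tes134 and Tes39. Adh1 and Adh2 did not (adjusted p = 0.879 and 0.915). The smallest adjusted p was shared by GI15361, GI19475 and GI12583 (8.98e-11 for each). Line means of GI15361 spanned 4.44 on the log2 scale in wrigleyi and 4.58 in sonorensis, and those of GI19475 spanned 4.86 and those of GI12583 3.47 in mojavensis, with SDs within lines of 0.33, 0.25 and 0.18. Over all targets, 27.8% of the variance lay between subspecies, 17.7% between lines and 54.5% between arrays of a line. Leaving out the lines of the 2 doubted arrays gave 35.2%, 21.2% and 43.6%. The count was 6425 without those arrays, 1599 without ANZA-0402-10, 1792 without CI-1002-27 and 4381 without OPNM-407-10.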

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

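The raw signal covariate, and the tests of raw signal and of single probes on the count of genes set apart in sonorensis, were chosen after that result had been seen, and the other tests in this part were set out beforehand. Each of the 11 counts of genes was compared with 100 splits of the lines into groups of the same sizes, the real split included. For each count only 1 split, the real one, gave as many genes, which argues against a chance split of the lines to the precision that 100 splits allow. The highest count of the other splits was 883 against 5545 among the 4 subspecies, 602 against 1917 for wrigleyi and mojavensis, 11 against 3143 for sonorensis and mojavensis, 19 against 707 for baja and mojavensis, 1692 against 5459 for sonorensis and wrigleyi, 77 against 262 for baja and wrigleyi, and 391 against 2404 for baja and sonorensis. For targets set apart it was 1 against 131 in mojavensis, 0 against 163 in wrigleyi, 1 against 12 in baja and 2 against 1247 in sonorensis. For each pair, only the lines of the 2 subspecies compared were split. For the count among the 4 subspecies and the counts of targets set apart, the lines of all 4 subspecies were mixed. The splits of the targets set apart therefore do not test whether a single subspecies stands apart while the others differ.

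Sonorensis was set apart in more targets than any other subspecies, and its arrays were the dimmest and among the last processed. With raw signal as a covariate 377 targets were set apart in sonorensis and 281 in wrigleyi, and sonorensis had the highest count in 15 of 22 fits that each left out 1 line (0.257 to 2.56 times the highest other count, lowest without MJBC-155), so raw signal and subspecies cannot be told apart as the cause, the covariate being confounded with the groups. Processing order predicted that late and early baja lines would differ the way sonorensis did, with a slope of at least 0.5, and the slope was -0.11 (other splits of the baja lines up to 0.435). The late lines were MJBC-35 and MJBC-103, and MJBC-103 holds a doubted array and was the brightest baja line (10.71). With so few lines, 1 of them unlike the others, the slope cannot decide on processing order. Single probes that depart by more than 1 are argued against as the whole cause, since without them 1347 targets were set apart in sonorensis and at most 159 in another subspecies. The differences of the targets set apart in sonorensis had a median size of 0.81, itself below that limit of 1. Median polish also limits the weight of a single departing probe beforehand. Smaller effects of sequence, or effects shared by the probes of a target, could not be judged. A difference between the subspecies remains open as an untested hypothesis.

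The Tes targets were lower in sonorensis as a group by camera with a preset correlation, but not with an estimated one (p = 0.0784, adjusted p = 0.627). Single probes that depart by more than 1 are argued against, since without them the median was -0.37 and the preset-correlation camera p was 5.9e-05. Smaller effects of sequence, or effects shared by the probes of a target, could not be judged. The shift of the group was itself smaller than that limit of 1. Lower raw signal stays open, since with the covariate the median was -0.11, against -0.37 without it, and the camera p was 0.339. A varying amount of testis tissue in the larval pools may also be a cause: the deviations of lines from their subspecies mean had a mean correlation of 0.219 between Tes targets, against an upper limit of 0.0546 from random lists matched on level. Differences in raw signal between lines could give such a correlation as well, so it does not separate these causes. A difference between the subspecies in the expression of these targets is open too and was not tested apart from these.

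Adh1 and Adh2 were highest in sonorensis and lowest in wrigleyi. All 8 of their probes were at least 1 higher in sonorensis on the log2 scale, between 1.70 and 2.20, which argues against single probes (the prediction had assumed 10 probes). Raw signal predicted a lost call or a much smaller difference for Adh2 between sonorensis and wrigleyi. The difference was 2.15 (SE 0.55) with the covariate and 2.07 without. In log2 median raw intensity, however, the brightest sonorensis line (9.80) lay below the dimmest wrigleyi line (10.02). The covariate therefore cannot separate raw signal from subspecies in this pair, and raw signal stays open. Calls in other pairs were lost. With the covariate, which is confounded with the groups, Adh1 did not pass against mojavensis (0.99, limma adjusted p = 0.0872). Neither gene then passed between baja and sonorensis (-1.36 and -1.48, adjusted p = 0.0825 and 0.0902). Cross-hybridization between the genes stays open as a source of their likeness, since line deviations were correlated at r = 0.964, which shared regulation could give as well. A difference between the subspecies is open as a hypothesis.

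In 25 of 184 groups of lines tested, 1 line lay far from the others of its subspecies, where chance gives about 1 in 20 groups of normally distributed values. The groups share lines, and Adh1 and Adh2 vary together, so an excess over that rate was not tested. Line ANZA-0402-5 of mojavensis was low in Adh1 (11.70) and Adh2 (12.52), CI-1002-6 of wrigleyi in Adh1 (11.20), and MJBC-155 of baja in Adh1 (11.52) and Adh2 (12.44). In each of these lines 1 array was far below the other. For Adh1 the arrays stood at 9.78 and 13.61 in ANZA-0402-5, 10.09 and 12.31 in CI-1002-6, and 9.46 and 13.59 in MJBC-155. OPNM-407-10 of sonorensis was low in Adh2 (14.87), GI18000 (12.27) and GI14479 (11.30) and high in Tes134 (9.76), and the correlation between its arrays was low (0.794).

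Line ANZA-0402-4 of mojavensis was low in Tes118 (9.07) and GI18617 (8.28) and high in GI14738 (13.80) and GI14556 (13.50). Line ANZA-0402-10 was low in Tes127 (9.03) and high in GI15361 (9.15), GI14480 (9.73) and GI18936 (12.55). In wrigleyi, CI-1002-3 was low in Tes114 (9.00) and high in GI20893 (9.96), CI-1002-6 was low in GI24425 (7.89), and CI-1002-27 was high in GI18617 (11.89). In baja, MJBC-103 had a high log2 median raw intensity (10.71). In sonorensis, OPNM-407-8 was high in Dscam (12.47) and OPNM-407-3 in GI15361 (12.29).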

How the results depend on the processing

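Omission of the 2 doubted arrays, raw signal as a covariate, draws of 4 lines, the first day alone and the RMA background were chosen after seeing the data, and the other alternatives were planned. Counts stayed within 1.5 times their value with no background correction, no offset, the RMA background, the mean of the probes, omission of departing probes, and trended robust moderation. The variance share was 28.6% with raw signal as a covariate. Adh1 and Adh2 kept their difference between sonorensis and wrigleyi in 40 of 40 alternatives (1.24 to 2.23 and 1.53 to 2.41). Of 47 differences of named targets, 24 passed with raw signal as a covariate, 31 with the extraction day block and 32 on the first day alone. With no control probes, signal over background could not be judged for dim targets. Except where fewer lines, arrays or targets or a stricter threshold account for a change by construction, the cause was not tested.

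Whether the replicate numbers pair the arrays of different lines was not settled, since no chance range was computed for the correlations. Their median was 0.126 over 231 pairs of lines (-0.722 to 0.822), with 129 pairs over 0.1. In most lines Adh1 and Adh2 were higher on replicate 1 than on replicate 2. With a replicate block and the line as random block, 36 targets were set apart in baja, 6172 differed among subspecies and 3091 among lines. With the line as random block alone 38 were set apart in baja. With the extraction day block 22 were set apart in baja and 106 in wrigleyi, and 4610 differed among lines.

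With 44 arrays as independent, the counts were 1607 for baja and mojavensis, 655 for baja and wrigleyi, and 301, 266 and 86 set apart in mojavensis, wrigleyi and baja. With array weights they were 8431 among subspecies, 4211 for wrigleyi and mojavensis, 5542 for sonorensis and mojavensis, 1346 for baja and mojavensis, 679 for baja and wrigleyi, and 366, 427, 60 and 1912 set apart in mojavensis, wrigleyi, baja and sonorensis. With cyclic loess they were 1282 for baja and mojavensis, 521 for baja and wrigleyi, 243, 307 and 29 set apart in mojavensis, wrigleyi and baja, and 4651 among lines. With median scaling they were 303 for baja and mojavensis, 165 for baja and wrigleyi, and 76 and 102 set apart in mojavensis and wrigleyi, and CtBP reversed in sonorensis (0.030).

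In the deposited table without normalization, the counts were 3328 for wrigleyi and mojavensis, 1394 for baja and mojavensis, 8333 for sonorensis and wrigleyi, 48 for baja and wrigleyi, 6898 for baja and sonorensis, 64, 29 and 2751 set apart in mojavensis, wrigleyi and sonorensis, and 4172 among lines. The Tes median in wrigleyi was 0.40 and no longer passed (p = 0.346), and moj30 (-0.061), moj9 (-0.046) and Tes14 (-0.13) reversed in sonorensis. Differences in brightness between arrays remain in that table by its construction.

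With raw signal as a covariate, the counts were 3605 for wrigleyi and mojavensis, 1783 for sonorensis and mojavensis, 1714 for baja and mojavensis, 607 for baja and wrigleyi, 1152 for baja and sonorensis, and 281 and 377 set apart in wrigleyi and sonorensis. The Tes medians were -0.11 in sonorensis (p = 0.339) and 0.060 in wrigleyi (p = 0.751), and Tes106 (0.42), Tes120 (0.16) and Tes124 (0.056) reversed in sonorensis. With an estimated correlation the Tes medians stayed at -0.37 (p = 0.0784) and 0.20 (p = 0.218) and no longer passed.

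Without the 2 doubted arrays, the counts were 2142 for baja and mojavensis, 711 for baja and wrigleyi, 282, 255, 83 and 757 set apart in mojavensis, wrigleyi, baja and sonorensis, and 6425 among lines. On the first day alone they were 1092 for wrigleyi and mojavensis, 133 for baja and mojavensis, 41 and 5 set apart in mojavensis and baja, and 10571 among lines, where the doubted arrays stood alone for their lines. Without dim targets they were 2007 for sonorensis and mojavensis and 735 set apart in sonorensis. In fits of 2 subspecies alone they were 311 for baja and mojavensis and 753 for baja and sonorensis.

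With a log2 difference of at least 1, the counts were 1585 among subspecies, 423 for wrigleyi and mojavensis, 489 for sonorensis and mojavensis, 186 for baja and mojavensis, 1235 for sonorensis and wrigleyi, 121 for baja and wrigleyi, 568 for baja and sonorensis, and 32, 61, 4 and 197 set apart in mojavensis, wrigleyi, baja and sonorensis. With 4 lines per subspecies the medians were, in the same order, 2789.5, 640, 1099, 238.5, 3475.5, 106 and 1424.5, and 40, 57, 4 and 498.5 set apart.

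With each line left out in turn, counts ran from 1267 (ANZA-0402-4) to 2456 for wrigleyi and mojavensis, 284 (MJBC-155) to 1077 (OPNM-407-10) for baja and mojavensis, 149 (CI-1002-9) to 530 (OPNM-407-10) for baja and wrigleyi, and 1115 (MJBC-103) to 3025 for baja and sonorensis. Targets set apart ran from 85 (MJBC-155) to 166 in mojavensis, 84 (CI-1002-9) to 311 (OPNM-407-10) in wrigleyi, 7 (MJBC-103) to 35 (OPNM-407-10) in baja, and 623 (MJBC-103) to 1520 in sonorensis. Targets that differed among lines ran from 1599 (ANZA-0402-10) to 4381 (OPNM-407-10). The other lines whose omission moved a count by over 1.5 times were MJBC-35 (174 for baja and wrigleyi, 88 set apart in wrigleyi and 34 in baja), MJBC-155 (169 for baja and wrigleyi, 1418 for baja and sonorensis, 107 set apart in wrigleyi and 826 in sonorensis), MJBC-216 (96 set apart in wrigleyi and 25 in baja), CI-1002-6 (174 for baja and wrigleyi, 102 set apart in wrigleyi), CI-1002-23 (164 and 100), CI-1002-27 (1792 among lines) and OPNM-407-2 (820 set apart in sonorensis).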

Other observations

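The test of identifier order in this part was chosen after its result had been seen, and the Adh comparison of arrays was made after the levels had been seen. Between the 2 arrays of a line, Adh1 and Adh2 differed together: over the 22 lines their differences had Pearson's r = 0.980 and Spearman's rho = 0.944 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Without the 2 lines farthest from the median r was 0.921. The lowest arrays stood at 9.75, 10.18 and 10.49 for Adh2, and the other arrays of those lines at 15.14, 14.86 and 13.63.

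Targets with consecutive GI numbers had slightly more similar profiles over the 4 subspecies than targets in random order. The mean cosine of their centred profiles was 0.0958 over 14125 pairs, against at most 0.0179 in 1000 random orders, so a chance order of the numbers is argued against. The mean was 0.0526 at 2 numbers apart, 0.0218 at 5, 0.0309 at 10 and 0.0153 at 100. If the numbers follow the order of genes in the genome, which was not tested, neighbouring genes may differ together between subspecies, and similar sequences of neighbouring genes remain another possible explanation.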
